A study of Mus musculus with 9 samples.

How the data were processed

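RNA was sequenced from 3 epithelium, 3 mesenchyme and 3 cyclopamine-treated whole intestine samples of mouse embryos. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.13, the build was mm9 and DESeq was used, without a version. The counting program, its strand setting and the annotation are not given in the sources used here, so genes that overlap, share an antisense partner or have a close copy (such as the alpha globins) are uncertain. The authors deposited whole read counts for 24016 RefSeq identifiers in 2 tables, and the 6 epithelium and mesenchyme columns are identical in both. The authors also deposited group means, a signal made of counts over size factors; dividing the counts by median-of-ratios factors over the 9 libraries gave all 4 deposited group means to within 1e-09. The deposited ratio, or fold, is the second mean over the first, and the deposited p-values and adjusted p-values are those of the authors' test, per the file headers. A further 2 deposited columns mark genes in text: the mark for higher in mesenchyme equals the authors' own calls at least 2-fold up for all 3967 genes, and 119 genes carry a muscle mark.

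The mean columns of the cyclopamine table hold mesenchyme first and treated whole intestine second. The comparison planned before the data were examined was treated against untreated whole intestine; the deposited one has untreated mesenchyme in its place, and untreated whole intestine was not analysed here. Deposited values are printed as the authors gave them, with the log2 of the deposited fold, and without an error of their own. Spreadsheet software had turned 27 symbols into date numbers, and all 27 were named through RefSeq accessions with the GRCm38 gene table, used for names and for which genes neighbour each other. No coordinates are given because that build differs from the authors' build.

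Epithelium and mesenchyme were compared on the deposited counts with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM normalization, quasi-likelihood fit and F test, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values use the TMM-scaled library size. A log2 difference is epithelium minus mesenchyme, or treated minus mesenchyme, and its SE is its size over the square root of F. In all, 31 gene lists fixed beforehand were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one, and with fry. For the deposited cyclopamine comparison, a list's median was placed among 10000 random lists of the same size matched on deciles of level, as a description. Compartment shares were compared with Fisher's exact test.

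Named genes follow a rule written before the data were examined. For the tissue layers these were the 12 largest log2 differences per direction among genes past the threshold, with no overlap of the 3 and 3 values and at least 10 CPM in the higher group. For cyclopamine they were the 12 largest finite deposited log2 differences per direction with a deposited mean of at least 100. Up to 4 members past the threshold were taken from each list, and 25 hedgehog, BMP, PDGF, Wnt and cell type genes were always included. Not every gene the rule picks is described. Genes outside the rule are marked as chosen after their values were seen.

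Chosen after seeing the data were an edgeR fit of all 9 libraries and a test for genes outside both layers, which takes the larger of the 2 p-values where treated intestine differs the same way from epithelium and mesenchyme. Genes were called enriched in a layer at 8-fold or more. On simulated counts with known changes the layer test recovered 12% of 2-fold and 85% of 4-fold changes with 3 false calls over 15075 genes. The test outside both layers recovered 40% and 81% with 0 false calls over 15523 genes. Only the changed genes differed between the simulated groups, whereas most real genes differ between the layers. Recovery may thus differ in the data, and false calls outside both layers were not measured under real layer differences. Depth limits the precision: mesenchyme 1 holds 3284702 counts outside Rn45s, Lars2 and Mir6236, and the others 14122486 to 26302836. Replicates were compared by chi-square per degree of freedom, from 9.70 to 1440, so no libraries agree within sampling noise. Alternatives changed the scaling, filter, test, threshold, covariates and libraries, and removed GC and length trends with an offset.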

Results

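The series measured gene expression by RNA sequencing in intestines of wild type C57BL/6 mouse embryos at stage E14.5, when the tube holds an inner epithelium inside a mesenchyme of fibroblasts, muscle precursors, neurons and vessels. Per the series design, intestines were kept for 24 hours in transwell culture. The sources used here do not say whether the separated layers were cultured as well, so treated intestine may differ from them in culture too. The files held 9 libraries in 3 groups of 3: separated epithelium, separated mesenchyme and whole intestine treated with cyclopamine, a plant alkaloid that blocks Smoothened and so the hedgehog pathway. Untreated whole intestine was not analysed here. Total counts were 22836297, 21866361 and 19934048 in epithelium 1 to 3, 9739394, 19614656 and 26357115 in mesenchyme 1 to 3, and 15588796, 14325792 and 18274881 in treated intestine 1 to 3. In mesenchyme 1 the ribosomal precursor Rn45s took 59.06% of counts (95% Wilson interval 59.03% to 59.09%, for counting error only), against 0.112% to 1.19% in the other libraries. Without Rn45s, Lars2 and Mir6236 that library held 3284702 counts. The labels do not say whether each library came from its own embryo or from a pool. Each library held Xist or Y-linked counts with only traces of the other, which argues against pools of both sexes. Epithelium 3 held 63360 Xist and 0 Ddx3y counts, and epithelium 2 held 36 and 2002. Pools of 1 sex stay possible. Every group held libraries of both sexes by their Xist and Y-linked counts, so its replicates include different animals, and p-values measure the spread between these libraries.

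The first comparison asked how the 2 tissue layers differ. Of 15141 genes tested, 4429 were higher in epithelium and 5064 higher in mesenchyme by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Differences of at least 16-fold were called for 455 genes in epithelium and 1193 in mesenchyme. The 3 epithelium and 3 mesenchyme values did not overlap for 72.8% of genes, where chance gives 10%. Separation was not complete: mesenchymal marker transcripts in epithelium 1, 2 and 3 stood at a median of 8.16%, 2.5% and 1.17% of their level in mesenchyme. Epithelial markers in mesenchyme 1, 2 and 3 stood at a median of 4.37%, 3.79% and 2.59% of their level in epithelium.

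Epithelial identity genes marked the first layer. Of 26 epithelial markers, 25 were higher in epithelium and none in mesenchyme. Epcam, a cell adhesion molecule, averaged 748 ± 29.4 CPM (SD, n = 3) in epithelium and 19.9 ± 1.28 CPM in mesenchyme, a log2 difference of 5.23 (SE 0.16, edgeR adjusted p = 1.37e-05). Cdh1, which encodes E-cadherin, differed by 5.25 (SE 0.22), and Vil1, which encodes the microvillus protein villin, by 5.76 (SE 0.36). Among 19 gut endoderm transcription factors, 16 were higher in epithelium, led by Gata4 (log2 5.73, SE 0.31), Hnf4g (5.46, SE 0.43) and Cdx2 (5.42, SE 0.54), while Sox2 was higher in mesenchyme at a low level (log2 -4.46, SE 0.53). Enterocyte and secretory genes were higher in epithelium for 21 of 26 tested, among them the lipid carriers Apob (5.82, SE 0.38), Fabp2 (5.73, SE 0.41) and Fabp1 (5.63, SE 0.77). The antimicrobial lectin Reg3b had the highest epithelial log2 difference under the naming rule, 7.67 (SE 1.86), and its CPM was spread widely over the epithelium libraries, at 858 ± 1217 (SD, n = 3). Reg3g, of the same family, came second with like spread, at 33.8 ± 48.5 CPM in epithelium (log2 6.98, SE 1.67). Areg, an EGF receptor ligand, ranked next without such spread, at 123 ± 17.8 CPM against 1.57 ± 1.32 (log2 6.78, SE 0.55). Adjusted over the list alone, the counts of these 3 lists were also 25, 16 and 21 higher in epithelium. Camera placed the lists above other genes (adjusted p = 5.5e-29, 3.1e-08 and 1.5e-08). With an estimated correlation the adjusted p was 0.27, 0.29 and 0.29.

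The mesenchyme carried the transcripts of many cell types. Fibroblast and mesenchyme markers were higher in mesenchyme for 31 of 33 tested, with Foxf2 at log2 -5.28 (SE 0.43) and Snai2 at -5.29 (SE 0.68); the exception past the threshold was Barx1, a transcription factor near the detection limit, at 3.43 (SE 0.55). Smooth muscle genes were higher in mesenchyme for 20 of 21, including Acta2 (log2 -4.61, SE 0.57), Myh11 (-4.92, SE 0.89) and the muscle coactivator Myocd (-5.58, SE 0.86). Of 25 enteric neural crest and neuron genes, 24 were higher in mesenchyme, with the endothelin receptor Ednrb at -4.91 (SE 0.45) and the neuropeptide Vip at -4.69 (SE 0.38), and Erbb3 was higher in epithelium (2.49, SE 0.16). Endothelial genes were higher in mesenchyme for 19 of 20 and macrophage and leukocyte genes for 18 of 18. Among interstitial cell of Cajal genes, which mark pacemaker cells, 6 of 7 were higher in mesenchyme. Mesothelial genes were higher in mesenchyme for 8 of 11 and erythroid genes for 7 of 9. Camera called the fibroblast, smooth muscle, neural, endothelial, leukocyte and Cajal lists (adjusted p from 5.9e-10 to 0.03), but not the erythroid (0.0502) or mesothelial (0.135) lists. With an estimated correlation the adjusted p of these 6 called lists lay between 0.29 and 0.42, and that of the erythroid list was 0.42. At the preset correlation the erythroid list passed without epithelium 2 (0.00563), epithelium 3 (0.0338), mesenchyme 2 (0.0275) or mesenchyme 3 (0.00532). It also passed with replicate number as a block (0.00136), with sex as a term (0.0399) and with GC and length trends removed (0.0463). The Cajal list did not pass without mesenchyme 1 (0.0811). Adjusted over the list alone, the counts were as given, except that 2 mesothelial genes were higher in epithelium.

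Hedgehog signals and their receivers lay on opposite sides. The ligands Shh (90.7 ± 40.2 CPM against 4.56 ± 3.77, log2 4.49, SE 0.92) and Ihh (5.07, SE 0.58) were higher in epithelium, while Scube1, Scube2 and Scube3, which help release the ligands, were higher in mesenchyme. All 15 hedgehog receptors and transducers were higher in mesenchyme. Gli1, a transcription factor and pathway target, averaged 203 ± 14.4 CPM in mesenchyme against 6.16 in epithelium (log2 -5.03, SE 0.60). The ligand-binding proteins Ptch1 (-3.40, SE 0.38) and Hhip (-5.21, SE 0.92) were likewise higher in mesenchyme, and Smo, which encodes Smoothened, differed less (-1.17, SE 0.14). Of 18 hedgehog response genes, 17 were higher in mesenchyme, including Foxf1 (-5.11, SE 0.55) and Foxl1 (-5.10, SE 0.47). By camera the receptor and response lists had adjusted p = 2e-05 and 2.7e-05. Their adjusted p was 0.29 and 0.31 with an estimated correlation. The ligand list went both ways and was not called (0.31). Adjusted over the list alone, 4 ligand list members were higher in mesenchyme and 1 response gene was higher in epithelium.

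**Figure D1:**
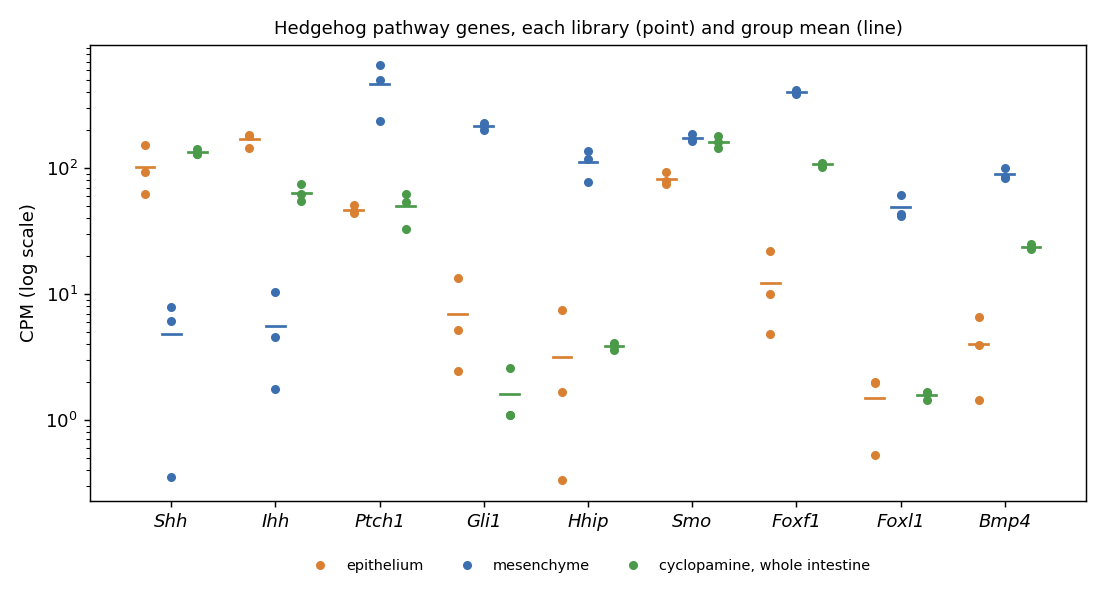
CPM of hedgehog pathway genes on a log axis in each of the 9 libraries, with a horizontal line at each group mean (n = 3). Shh and Ihh are high in epithelium, and Gli1, Hhip and Foxl1 in cyclopamine-treated whole intestine lie far below their level in mesenchyme.

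Other signalling genes were mostly mesenchymal. Among BMP ligands, 9 of 12 tested were higher in mesenchyme, with Bmp4 at log2 -4.57 (SE 0.50), Bmp5 at -4.67 (SE 0.55), Bmp7 at -2.15 (SE 0.18) and Bmp2 at -1.46 (SE 0.27), and Bmp8b was higher in epithelium (2.98, SE 0.71). All 20 BMP antagonists and modulators tested were higher in mesenchyme, including Nog (-5.34, SE 0.55), Grem1 (-5.55, SE 0.73) and Chrdl1 (-5.83, SE 0.32), and 12 of 17 BMP receptors and effectors were. In the PDGF pathway the ligand Pdgfa was higher in epithelium (1.18, SE 0.16) and the receptor Pdgfra in mesenchyme (537 ± 112 CPM against 16.8 ± 15.3, SD, n = 3), as were 5 of 7 members in all. All 9 Wnt ligands and R-spondins tested were higher in mesenchyme, including Wnt5a (-4.57, SE 0.75) and Rspo3 (-5.13, SE 0.56). Wnt receptors and inhibitors split 13 to 5 in favour of mesenchyme and Wnt response genes 7 to 5. Lgr5, a Wnt target and stem cell marker, was higher in epithelium (3.42, SE 1.05, edgeR adjusted p = 0.0241), a call lost without epithelium 3 (2.54), mesenchyme 2 (2.92) or mesenchyme 3 (2.74). Axin2 did not pass (-0.29, SE 0.44). FGF genes were higher in mesenchyme for 9 of 16, Notch genes for 13 of 17 and planar cell polarity genes for 12 of 19. Adjusted over the list alone, 13 BMP receptors and effectors and 14 Notch genes were higher in mesenchyme, and the other counts were as given. Camera called the BMP lists (adjusted p = 0.0051, 3.1e-08 and 0.00061), Wnt ligands (0.00038), Wnt receptors (0.012), Notch (0.00095) and planar cell polarity (0.012). With an estimated correlation the adjusted p of these 7 lists was 0.29 or 0.42. The PDGF (0.23), FGF (0.068) and Wnt response (0.71) lists were not called. The FGF list passed without mesenchyme 2 (0.039) or mesenchyme 3 (0.0428). The Wnt receptor list did not pass without mesenchyme 1 (0.0506) or with GC and length trends removed (0.0662), nor the polarity list with those trends removed (0.0968).

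Among the remaining lists, basement membrane genes were higher in mesenchyme for 14 of 19, led by Lama2 (log2 -5.45, SE 0.77), while Lamb3 was higher in epithelium (4.79, SE 0.41). Hox genes were higher in mesenchyme for 21 of 24, with Hoxc4 at -5.47 (SE 0.32). Cell cycle genes were higher in epithelium for 15 of 28, including the replication clamp Pcna (1.15, SE 0.25), and in mesenchyme for 2. Cholesterol synthesis genes were higher in epithelium for 9 of 23. Hypoxia and glycolysis genes split 6 to 4 and immediate early and heat shock genes 7 to 9 between epithelium and mesenchyme. Pancreas and liver genes were higher in epithelium for 4 of 6. There were 8 cholesterol genes higher in epithelium when adjusted over the list alone, and 1 pancreas and liver gene was higher in mesenchyme, with the other counts as given. Camera called the basement membrane (adjusted p = 0.013), Hox (1e-10), cell cycle (0.039) and cholesterol (0.03) lists, with adjusted p = 0.35, 0.29, 0.66 and 0.63 with an estimated correlation. Without mesenchyme 1 the basement membrane (0.0707), cell cycle (0.0787) and cholesterol (0.0811) lists did not pass, nor did cell cycle without epithelium 3 (0.0564). With GC and length trends removed, the basement membrane (0.166) and cell cycle (0.0823) lists did not pass. The hypoxia (0.37), immediate early (0.52) and pancreas and liver (0.11) lists were not called, the last passing without mesenchyme 2 (0.0421) or with replicate number as a block (0.0438). Camera with the preset correlation of 0.01 called 22 of 31 lists in all. With an estimated correlation it called 0, with 3 lists at an unadjusted p under 0.05, while fry, which tests movement in 1 direction without reference to other genes, called 29.

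**Figure D2:**
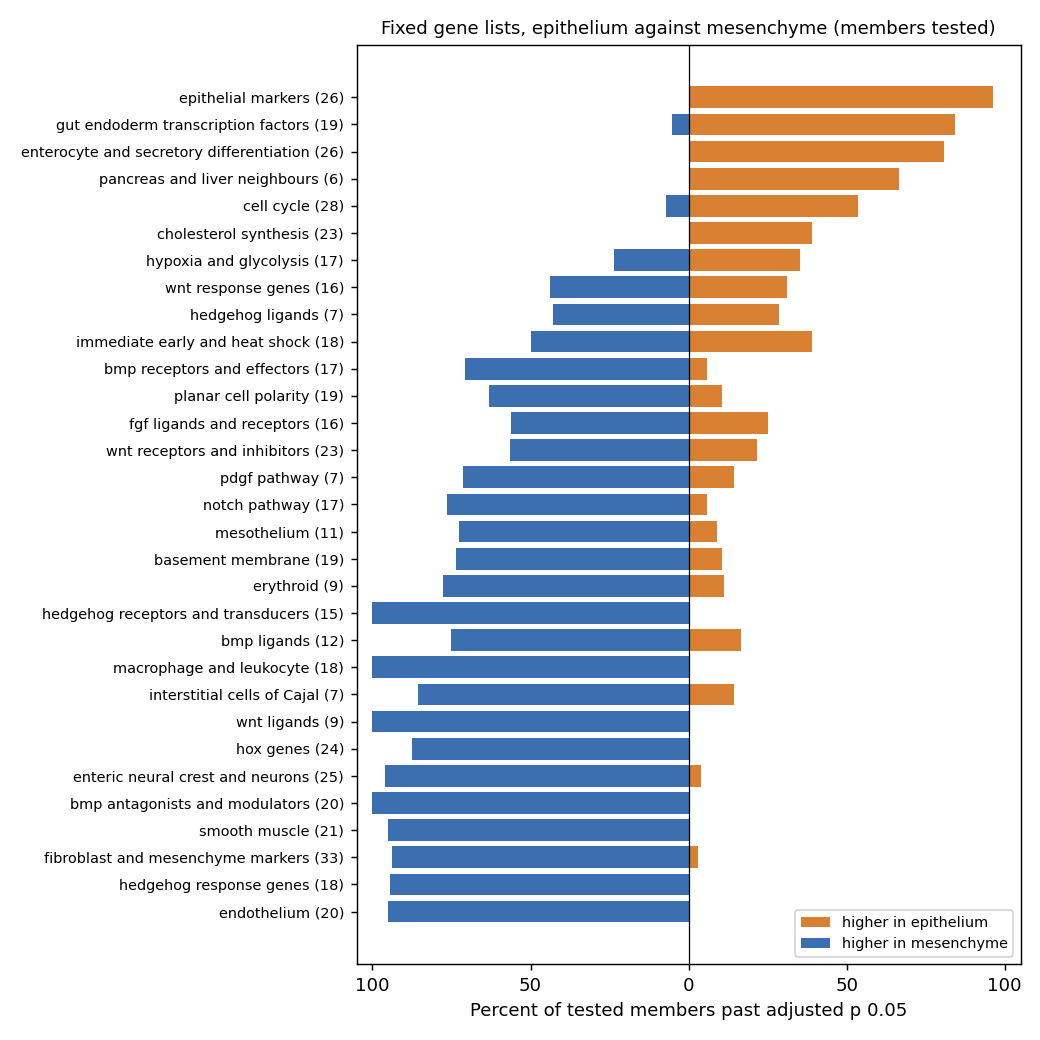
For each of the 31 gene lists, the percent of tested members higher in epithelium (right) or in mesenchyme (left) at an edgeR adjusted p under 0.05, with the number tested in brackets. Epithelial markers stand at 1 end, with 25 of 26 higher in epithelium, and all 20 BMP antagonists are higher in mesenchyme.

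The second comparison concerned cyclopamine. The authors' deposited table compares treated whole intestine with untreated separated mesenchyme, as its means show, so a difference can stem from epithelium in the whole tissue as well as from treatment. The authors' deposited table called 1992 genes higher and 1943 lower in treated intestine at an adjusted p under 0.05. Epithelial genes were higher: the authors' deposited table called 25 of 26 epithelial markers, 16 of 19 endoderm transcription factors and 15 of 30 enterocyte and secretory genes higher, with Epcam at a log2 difference of 4.48 and Shh at 4.73.

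Hedgehog targets were among the genes with the lowest values. Gli1 went from a deposited mean of 3808 normalised counts in mesenchyme to 27.6 in treated intestine, a log2 difference of -7.11 in the authors' deposited table (adjusted p = 2.39e-132). The authors' deposited table gave Foxl1 at -4.98, Hhip at -4.90 and Ptch1 at -3.27, while Smo, at -0.14, did not pass. Of 15 receptors and transducers the authors' deposited table called 8 lower and none higher, and of 21 response genes 12 lower and none higher. Adjusted over the list alone, these counts in the authors' deposited table were 10 and 13. The receptor list's median log2 difference was -1.04 and the response list's was -1.24, both at percentile 0 of 10000 random lists matched on level. Those random lists came from all genes, and the fibroblast, endothelial, BMP antagonist, basement membrane and Hox lists also stood at percentile 0. The percentile thus does not separate hedgehog targets from other genes high in mesenchyme. Other genes named by size in the authors' deposited table were Kcng1, a potassium channel subunit (-5.35), Ranbp3l (-5.21), Col6a4 (-4.72) and Procr (-4.47).

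Treated whole intestine differed from mesenchyme in cell type markers too. Of 34 fibroblast and mesenchyme markers, 19 were lower in the authors' deposited table, among them Foxf2 (-2.89) and Col6a2 (-2.65), and 14 of 20 endothelial genes, such as Plvap (-2.60). By contrast, smooth muscle genes were lower for 4 of 21 and higher for 1, Hspb7, with Acta2 (-0.60) and Myh11 (-0.41) not past the threshold in the authors' deposited table. Of 26 enteric neural genes the authors' deposited table called Ednrb lower (-1.21) and Erbb3 higher (0.89). Macrophage and leukocyte genes were lower for 2 of 19 and higher for 1, Mrc1 (1.05), in the authors' deposited table. Cajal genes were lower for 3 of 7, including Ano1 (-2.53), in the authors' deposited table. Erythroid genes were higher for 6 of 15, with embryonic globin Hbb-y at 2.09, mesothelial genes for 2 of 11 and pancreas and liver genes for 5 of 14 in the authors' deposited table. Of 119 genes that carry the authors' muscle mark, whose choice is not explained in the sources used here, 52 were lower and 1 higher in the authors' deposited table. All 119 also carry the mark for higher in mesenchyme, and their median log2 difference was -0.7 in that table. Lower values can thus stem from epithelium in the whole tissue. The study chose these genes, so their direction is not independent evidence.

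BMP ligands and antagonists were lower where they passed. The authors' deposited table called 5 of 15 ligands lower, including Bmp3 (-2.82), Bmp4 (-1.96) and Bmp5 (-1.24), and 12 of 22 antagonists, including Grem1 (-1.83) and Nog (-1.19). For BMP receptors and effectors 3 of 19 were lower and 2 higher in the authors' deposited table. Basement membrane genes were lower for 14 of 21 and higher for 2, with Lama5 at -2.37 and Col4a1 at -2.15 in the authors' deposited table. Notch genes were lower for 8 of 18 and higher for 1, Hes6, planar cell polarity genes for 5 of 19, Hox genes for 6 of 36, FGF genes for 3 of 24 with 2 higher, PDGF genes for 2 of 7 and Wnt ligands for 2 of 21 in the authors' deposited table. Wnt receptors split 5 higher to 4 lower and Wnt response genes 5 to 3, with Lgr5 at 2.86 in the authors' deposited table. Hedgehog ligands split 2 to 2, with Disp1 listed at 0 in treated intestine, hypoxia and glycolysis genes 5 to 2 and immediate early genes 1 to 1 in the authors' deposited table. Disp1 also had 0 counts in untreated mesenchyme 1, so its 0 does not show an effect of treatment. Cholesterol synthesis genes were higher for 18 of 24 and lower for none, including Idi1 (2.24) and Msmo1 (1.71) in the authors' deposited table. Cell cycle genes were higher for 7 of 28 there, led by Ccnb1 (1.24). The authors' deposited table had, adjusted over the list alone, 20 cholesterol genes higher, and 21 fibroblast, 16 endothelial, 15 basement membrane and 13 BMP antagonist genes lower. In every other list not yet given so, its counts differed by at most 2. Of the 31 lists, 18 had a median outside the middle 95% of matched random lists.

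The calls followed the tissue layers. Of 1938 genes lower in the authors' deposited table, 64.8% were mesenchyme-higher, against 33.5% of 11229 uncalled genes (odds ratio 3.65, 95% interval 3.29 to 4.04, Fisher's exact test, two-sided, p = 1.77e-146). Of 1974 genes higher in the authors' deposited table, 85.4% were epithelium-higher, against 23.2% of uncalled genes (odds ratio 19.3, 95% interval 16.9 to 22.1, Fisher's exact test, two-sided). Whole intestine holds epithelium and separated mesenchyme largely does not, so both shares would be raised without any effect of cyclopamine. They do not measure a response to treatment. Genes are not independent replicates, and both comparisons share the mesenchyme libraries. At an unadjusted p under 0.05 in both, 1892 genes were lower and mesenchyme-higher, against 1047 for independent lists, and 2220 were higher and epithelium-higher, against 864.7. In 20 simulations with no effect at all, the overlaps at that p averaged 69.45 genes where independent lists would give 8.184, and 95.5 where they would give 8.433. Shared libraries alone thus raised the overlaps, and their part in the real ones cannot be separated with 3 mesenchyme libraries. At an adjusted p under 0.05 by edgeR no simulation gave an overlapping gene. With no effect present hardly any gene can pass adjustment, so this result was fixed beforehand and does not measure the part of shared libraries.

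A fit of all 9 libraries, chosen after seeing the data, set treated intestine against each layer. EdgeR called 3258 genes higher and 3211 lower than in mesenchyme (1972, 2019 and 2136 lower without treated library 1, 2 or 3), and 5034 higher and 4677 lower than in epithelium. Among 2102 genes at least 8-fold higher in mesenchyme than in epithelium, the median log2 difference of treated intestine from mesenchyme was -0.73. Against that background 8 hedgehog receptors and transducers had a median of -2.61 and 15 response genes of -1.90, both at percentile 0 of matched lists, with 4 genes in both lists. Over the 19 different genes the median was -1.27, at percentile 0.86, and without mesenchyme 3 it was -1.11, at percentile 2.56 and inside the middle 95% of matched lists. Basement membrane genes (-1.61, percentile 0.53) and BMP ligands (-1.48, percentile 2.16) also lay below the middle 95% of matched lists, while enteric neural genes stood at 0.02 and smooth muscle genes at -0.48, at percentiles 100 and 98.1. Erythroid genes stood higher still, with a median of 1.17 at percentile 100. Inside the middle 95% but low were polarity genes (-1.24, percentile 11.9), BMP antagonists (-1.17, 3.38), endothelial genes (-1.07, 4.7) and fibroblast markers (-1.06, 7.08). Notch genes (-0.69), Wnt ligands (-0.65), Cajal genes (-0.63) and Wnt receptors (-0.44) lay above the background median. Gli1 had the lowest value of the 2102 genes. Hhip, Ptch1 and Foxl1 in treated intestine differed from epithelium by 0.26 (SE 0.73), 0.09 (SE 0.34) and 0.07 (SE 0.41), none past the threshold in edgeR.

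**Figure D3:**
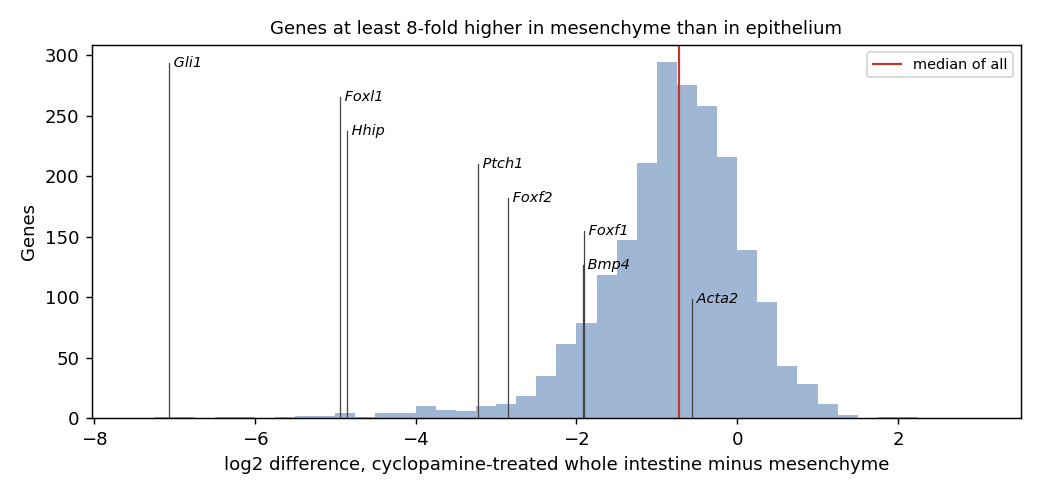
Histogram of the log2 difference between cyclopamine-treated whole intestine and mesenchyme for 2102 genes at least 8-fold higher in mesenchyme than in epithelium, with their median (-0.73, red) and named genes marked. Gli1, Foxl1 and Hhip lie at the left end, and Acta2 lies near the median.

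The same fit asked which genes lay outside the range of both layers. EdgeR called 601 genes below both and 195 above both, or 1442 and 776 at an unadjusted p under 0.05, and DESeq2 called 1025 and 370. Without treated library 1, 2 or 3 the counts were 125, 135 and 75 below and 42, 44 and 25 above, and without mesenchyme 1 they were 1036 and 411. Without epithelium 1, 2 or 3 there were 307, 275 and 323 below, and without epithelium 2 there were 109 above. Above both were 8 of 23 cholesterol synthesis genes, including Idi1 at 218 ± 25.2 CPM (SD, n = 3) against 72.8 in epithelium and 45.1 in mesenchyme, and Tm7sf2. That count was 15 without mesenchyme 1 and 5, 5 and 3 without treated library 1, 2 or 3. It was 15 when adjusted over the list alone. Further genes above both were the metal-binding protein Mt2, at 47.1 ± 16.1 CPM against 1.32 in epithelium, and the zinc exporter Slc30a1; Hbb-y of the erythroid list; Serpina1a (23.1 ± 1.58 CPM against 6.43 in epithelium) and Fgb of the pancreas and liver list; and Ccna2, Ccnb1 and Cenpf of the cell cycle list. Below both were Lama5, Lamb2 and Agrn of the basement membrane list, Dvl1, Dvl2 and Scrib of the planar cell polarity list, and Vegfa. Tm7sf2, Slc30a1 and the genes of this test outside the naming rule were chosen after their values were seen. Disp1, needed for hedgehog release, also lay below both, but it had 0 counts in mesenchyme 1 as well as in the 3 treated libraries. Mia3, Ppp2r3d and Dhrsx, with the largest differences below both, had 0 counts in the same libraries. With such genes left out, 475 genes lay below both and 252 above both. Separate processing of mesenchyme 1 and the treated libraries, or culture of whole tissue, can also place genes outside both layers. Neither can be told apart from treatment for these counts.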

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

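The 9-library tests, and the alternatives with GC and length trends removed, with sex as a term, or with Rn45s, Lars2 and Mir6236 or the genes at 0 left out, were chosen after seeing the data. The count of 9493 genes that differed between the layers stayed within 1.5 times under RLE and upper-quartile scaling, both filters, DESeq2 (10370), an adjusted p under 0.01 (7316) and the added settings; without 1 library it ran from 8309 to 11044, the highest without mesenchyme 1. A 2-fold minimum left 2605 genes higher in epithelium, by its own construction. With replicate number as a block the count was 9000. The numbers do not pair all samples: 1 of 3 libraries was female in epithelium and 1 of 3 in mesenchyme, under different numbers. Deviations of same-numbered libraries correlated at 0.08, 0.30 and -0.07, and epithelium 3 correlated best with mesenchyme 1. Pairs under other numbers were not fitted, so the block does not test whether layers came from the same intestines. The lists called by camera went from 22 to 0 with an estimated correlation and from 17 to 25 without 1 library. Alternatives for normalized values (median centring, quantile normalization, other pseudocounts, no filter on low values) were not run, because the tables hold counts.

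For the deposited cyclopamine comparison, a 2-fold minimum left 1297 higher and 1033 lower genes, and an adjusted p under 0.01 left 1272 lower genes; both are stricter by construction. In the 9-library fit the genes lower than in mesenchyme ran from 1972 to 3511 without 1 library. Genes below both layers ran from 75 to 1036 and genes above both from 25 to 411, lowest without cyclopamine 3 and highest without mesenchyme 1. DESeq2 called 1025 below and 370 above both; the cause was not tested. The median of hedgehog genes among mesenchyme-enriched genes ran from -1.69 to -1.11 without 1 library, and only without mesenchyme 3 did it leave the lowest 2.5% of matched lists, at -1.11; the cause was not tested. Of single genes, Axin2, which was not called, changed sign, at 0.08 without epithelium 2, 0.06 without mesenchyme 1 and 0.19 with GC and length trends removed, from a low of -0.75 without epithelium 3; the cause was not tested. Ttr lost its call without epithelium 2 (2.59) or mesenchyme 3 (2.29), Lgr5 without epithelium 3, mesenchyme 2 or mesenchyme 3, and Cenpa without epithelium 1 (-0.56), epithelium 2 (-0.58), mesenchyme 2 (-0.55) or mesenchyme 3 (-0.54), where fewer samples were tested. The other 2316 log2 differences under alternatives kept their direction and their side of the threshold.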

Other observations

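The 9-library fit behind the values of treated intestine, and the tests on zero counts, on mixing with epithelium and on members whose calls ended, were chosen after the result was seen. Among 737 genes at least 8-fold higher in epithelium, the median log2 difference of treated intestine from epithelium was -1.35. Picked from the lower end, Muc2, the goblet cell mucin, differed by -5.66 (SE 0.90, edgeR adjusted p = 0.000484), Agr2 by -3.17 (SE 0.60) and Fcgbp by -2.97 (SE 0.53), and the enterocyte disaccharidase Sis by -3.79 (SE 0.61). Reg3b differed by -10.21, with wide spread among the epithelium libraries. Other goblet cell genes varied: Tff3 at -1.52 and Hepacam2 at -1.58 lay near that median, and Clca3 at -3.35 lay far below it. No list of goblet cell genes alone was fixed beforehand. These genes were chosen after their values were seen. As a list, the 19 enterocyte and secretory genes enriched in epithelium had a median of -1.52, inside the range of matched lists.

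Hedgehog genes, like basement membrane genes and BMP ligands, lay below other mesenchyme-enriched genes in treated intestine. The BMP antagonist, endothelial and fibroblast lists came close, at medians of -1.17, -1.07 and -1.06, though inside their matched ranges. The low position was thus not particular to hedgehog genes. For the 19 receptors, transducers and response genes enriched in mesenchyme, the median log2 difference from mesenchyme was -1.27, below the range of -1.18 to -0.49 of matched lists, which argues against mixing with epithelium as the whole source. The median was -1.32 without the ribosomal-rich library mesenchyme 1 and -1.28 with GC and length trends removed, both below their matched ranges, but it reached the edge of the range, at -1.11, without mesenchyme 3. Separate processing cannot be told apart from treatment with 1 untreated library of that kind; in mesenchyme 1 the genes differed by 0.20 from the other mesenchyme libraries, away from the change. An effect of cyclopamine on hedgehog signalling may account for the pattern, as a hypothesis, and whole tissue culture without drug was not tested.

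A set of 16 genes, among them Mia3, Vamp7, Disp1 and Dhrsx, had 0 counts in mesenchyme 1 and in all 3 cyclopamine libraries and at least 15 counts in each of the other 5. The median count expected in mesenchyme 1 was 53.9, which argues against low depth. Choosing genes at 0 in the cyclopamine libraries without regard to mesenchyme 1 gave 16 genes, of which 16 were at 0 in that untreated library, which argues against cyclopamine. Of the 16 genes, 15 had another within 2 places on the chromosome, where 10000 random sets reached at most 4. Another annotation or reference for these 4 libraries may account for this, and a shared deletion in the animals would give neighbours too and was not tested. No other choice of 4 of the 9 libraries gave such a gene.

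Cholesterol synthesis genes lay above both layers in treated intestine for 8 of 23 members, with a median log2 difference of 0.96 from the nearer layer. Serpina1a and Fgb of the fixed pancreas and liver list also lay above both layers, so some liver tissue stays possible, but that list lay above epithelium by a summed 82.9 CPM, against 895 CPM for the 8 genes, and albumin stood at 0.794 CPM, which argues against liver as the whole source. With GC and length trends removed 5 of the 8 remained called, while the calls of Fdft1 (0.78, SE 0.14, to 0.57, SE 0.15), Cyp51 (0.89, SE 0.22, to 0.60, SE 0.19) and Hsd17b7 (0.66, SE 0.15, to 0.23, SE 0.14) ended as their differences shrank, so for these 3 such trends stay open. In mesenchyme 1 the 8 genes differed by -0.46 from the other mesenchyme libraries, but 1 library cannot settle separate processing. A response of sterol synthesis to the steroidal alkaloid, or to culture of whole tissue, may be followed up as a hypothesis; no untreated whole intestine was compared.

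Other splits of the samples were counted. The 3 against 3 comparisons have 10 splits each, too few for a share under 0.05; as large a count came from 1 split, the real one, with 9493 genes between the layers, 6469 between treated intestine and mesenchyme and 9711 between treated intestine and epithelium, against a highest other count of 0 in each. For camera's lists the real count was 22 and the highest other 24, with 6 of 10 splits as large. For genes outside both layers, 4 of 100 splits gave at least the real 796, and the highest other was 1489. All 95 splits with a mixed tested group gave 0, the 3 with the intact mesenchyme group gave 1446 or more, and 1 further split with the cyclopamine group intact but the layers mixed gave 0. The gene counts thus follow the structure of the samples and do not tell whether chance can be excluded. The list counts do not follow it: splits that mixed the layers called 0 genes but 12 to 24 lists. A count of 22 lists at the preset correlation is thus not particular to the layers.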
